A study of Mus musculus with 13 samples.

How the data were processed

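Single-cell RNA sequencing was done on myeloid cells sorted from the spinal cord of mice of the Cx3cr1YFPCreERT2:R26tdTomato line. In this fate-mapping line, a tamoxifen-inducible Cre recombinase expressed from the Cx3cr1 locus switches on the red fluorescent protein tdTomato, and long-lived resident microglia keep that mark while short-lived blood monocytes are replaced by unmarked cells. Resident and infiltrating cells were collected from mice with experimental autoimmune encephalomyelitis (EAE), an immune-driven model of inflammatory demyelination, at the peak or in the chronic phase of disease, and resident cells were also collected from healthy controls. Per the labels' protocols, spinal cords were dissociated mechanically in the cold, myelin was removed on Percoll and live cells were sorted by flow cytometry. The labels call the samples of a group biological replicates.

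The authors deposited a sparse matrix of counts, in which each value is the number of unique molecular identifiers (UMIs) of a gene in a cell, with no normalization. Per the submitters' processing notes, Cell Ranger 3.1.0 and R 4.1.3 were used with the mouse genome builds GRCm38 and mm10; the gene annotation is not given in the sources used here. A deposited table of cells gives each cell's library, sequencing pool, class and doublet status, its mitochondrial content as a percent, and the log10 of its total UMI count. In the deposited table the mitochondrial percent reached 5.00 and no further, the log10 totals matched the matrix, and 0 cells were marked as doublets. The matrix held 22598 features, among them 0 mitochondrially encoded genes, so the subunits of the respiratory chain made inside mitochondria were not measured here. A dense text copy of the same counts was not used here.

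The deposited cell table names the group of each library but not the replicate number of the labels, so libraries of a group are called a, b and c here, as names only. Samples were grouped by the labels as control resident (n = 3), peak EAE resident (n = 2), chronic EAE resident (n = 3), peak EAE infiltrating (n = 2) and chronic EAE infiltrating (n = 3). The 13 libraries were sequenced in 4 pools, called A to D here. Pool A held control a and peak infiltrating a; pool B held control c, chronic resident c and chronic infiltrating c; pool C held control b, both peak resident libraries and peak infiltrating b; pool D held chronic resident a and b and chronic infiltrating a and b. No pool held libraries of both disease stages, for resident or for infiltrating cells. The libraries of pools A, B and D carry 1 batch date each, and those of pool C carry 2, with control b and peak resident b on the same date.

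Cells are not replicates, so the UMIs of all cells of a library were summed per gene and the libraries were compared. The sums were tested with edgeR 4.0.16 in R 4.3.3, with filterByExpr by group (11787 genes left), TMM scaling, and the quasi-likelihood F test on 1 fit of 5 group means over the 13 libraries, which left 8 residual degrees of freedom. The fit had a biological coefficient of variation of 31.2%. P-values were adjusted with the Benjamini-Hochberg method over all genes tested, and genes with an adjusted p under 0.05 were called. Standard errors of log2 fold changes were derived from the F statistic. CPM, a count relative to the total of its library, was scaled by TMM for single genes and by library size alone for sums over a gene list. All tests were two-sided.

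The gene lists, the comparisons, the test and the rule for naming genes were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 on voom values, with the preset correlation between genes of 0.01, and again with an estimated correlation and with fry. With a library left out, only the preset correlation was used. Camera p-values were adjusted over the lists within each comparison. Beside the count of list members called over all genes, a count is given with p-values adjusted over the list alone. The lists cover the respiratory chain complexes and their assembly, metabolism, antioxidant genes, microglial states, antigen presentation, interferon and cytokine genes, lipid handling, proliferation, genes induced by dissociation, and markers of other cell types that the sort could hold. The endothelial list had only 2 tested members, the erythrocyte list only 1, and the lists of mitochondrially encoded genes 0, so no change is stated for them.

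The genes named are, for each comparison of 2 groups, up to 6 higher and 6 lower genes with the smallest p among called genes with an absolute log2 fold change of at least 1, an average log2 CPM of at least 5 and CPM values that do not overlap between the groups. To these come up to 4 members of each list described, and a fixed set that includes Cybb, Apoe, Spp1, Gpnmb, P2ry12, Tmem119, Ccr2 and Arg1. Ribosomal protein genes, predicted genes, Xist and Y-linked genes were left out of the naming. Features listed only by an identifier were counted and tested but not named. Some genes that the rule takes are not reported here. Symbols were matched to GENCODE mouse release 21 (GRCm38), in which 20572 of the 22598 features (91.0%) were found, for coordinates and transcript lengths. The counting was not described by strand in the sources used here, so genes that overlap or share near-identical copies, as the H2 genes do, are less certain.

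Cell classes are the 7 of the deposited annotation, and the cell table also gives 10 clusters. A class was compared between groups only where the 10 leading genes of each of its clusters, ranked by fold, did not point to another class. No class is natural killer cells, and Nkg7 and Gzma led the T cell cluster, so natural killer markers may reflect T cells. Among the clusters, 1 mixed 1749 cells annotated as macrophages with 1429 annotated as monocytes, and another of 139 cells, 125 of them annotated as monocytes, was led by neutrophil genes. These classes were therefore given only as a summed share per library. Shares were compared with an exact permutation test. Scrublet, run on each library through scanpy 1.11.5 in Python 3.11.15, called 113 cells (0.51%) doublets, kept except in an alternative.

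The same fit was tested on simulated data, with 200 of 11787 genes changed. Counts were drawn from each gene's mean over all libraries, the spread typical of genes at that mean, and the depths of the libraries. Changed genes were taken only from those above a minimum mean CPM. No difference between pools or in cell composition was simulated, so the values below apply to that simpler setting. A log2 fold change of 2 was recovered for 92% of genes in resident peak EAE against control, 96% in resident chronic EAE against control, 95% in resident chronic against peak EAE, 88% in infiltrating chronic against peak EAE, 82% in infiltrating against resident cells at the peak and 97% in infiltrating against resident cells in chronic EAE. For a log2 fold change of 1 the same comparisons recovered 16%, 22%, 16%, 15%, 14% and 30%, with 2, 5, 1, 4, 7 and 2 false calls.

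Alternatives fixed before the data were examined were RLE size factors, DESeq2 1.42.0, limma-voom, no filter on low counts, a fit of only the groups compared, only cells of the sorted class (microglia in resident, monocytes and macrophages in infiltrating libraries), removal of Scrublet doublets, thinning to the smallest library (4111257 UMIs) and leaving out each library in turn. Where leaving out a library left 1 library in a group, that library was assumed to vary like the other groups. Annotated classes come from the same expression values, so differences in marker genes over cells of the sorted class are set in part by the annotation. Alternatives added after seeing the data were the sequencing pool as a term (5 residual degrees of freedom), alone or with only cells of the sorted class, scaling by library size only, removal of microglia from the infiltrating libraries, pairs of chronic libraries as a block, and leaving out chronic infiltrating library b from every comparison. The pairs came from the pool and the similarity of microglia, since the planned pairing by replicate number could not be made.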

Results

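The data held 22148 cells and 116091839 UMIs in 13 libraries of cells sorted from mouse spinal cord. Resident cells came from healthy controls (3 libraries, 6205 cells), from the peak of EAE (2 libraries, 1267 cells) and from chronic EAE (3 libraries, 8771 cells). Infiltrating cells came from the peak (2 libraries, 2381 cells) and from chronic EAE (3 libraries, 3524 cells). Library totals ran from 5462980 to 10439490 UMIs in control resident, 4654613 to 6728837 in peak resident and 7680353 to 18846457 in chronic resident libraries. They ran from 4922059 to 22450385 in peak infiltrating and 4111257 to 10168132 in chronic infiltrating libraries. Median UMIs per cell were 3020 to 4477 in control, 8614 to 8648 in peak resident, 2558 to 3560 in chronic resident, 10765 to 11146 in peak infiltrating and 2913 to 8208 in chronic infiltrating libraries. Single cells held between 802 and 63100 UMIs. The study's title names mitochondrial reverse electron transport, a process in which electrons flow backwards into respiratory complex I, so complex I genes are given for each comparison. CPM values are mean ± SD over the libraries of a group, and log2 fold changes are ± SE from edgeR's quasi-likelihood test with Benjamini-Hochberg adjusted p.

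In the deposited annotation, microglia, the resident macrophages of the spinal cord, made up 98.6%, 99.6% and 99.4% of cells in the control libraries, 91.5% and 95.7% in the peak resident libraries and 93.5%, 90.6% and 97.3% in the chronic resident libraries. Monocytes and macrophages together made up 87.7% and 82.4% of cells in the peak infiltrating libraries and 82.8%, 14.5% and 51.5% in the chronic infiltrating libraries. Microglia made up 1.80%, 81.2% and 13.4% of chronic infiltrating libraries a, b and c, so library b of that group held mostly microglia. T cells were 0.0288% ± 0.0279 of control resident cells, 1.24% ± 0.162 of peak resident cells and 3.16% ± 2.73 of chronic resident cells. Microglia were 99.2% ± 0.510, 93.6% ± 2.92 and 93.8% ± 3.40 of the same groups. Against control, T cell and microglial shares each gave an exact permutation p of 0.1 at both stages, the smallest that these numbers of libraries allow. Between chronic and peak resident libraries the exact permutation p was 0.6 for T cells and 1 for microglia, whose shares differed by 0.227 percentage points. That difference was -1.84 without peak resident library a and -1.54 without chronic resident library c. It was 2.29 without peak resident library b, and 1.85 and 0.370 without chronic resident libraries b and a. In infiltrating libraries, chronic against peak shares were 5.35% ± 3.57 against 9.05% ± 2.56 for T cells and 12.1% ± 11.5 against 5.04% ± 1.69 for dendritic cells. For microglia they were 32.1% ± 42.9 against 0.693% ± 0.327. The exact permutation p was 0.3, 0.6 and 0.5. The sort set which cells were collected, so shares describe the sorted cells and not the tissue.

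**Figure D1:**
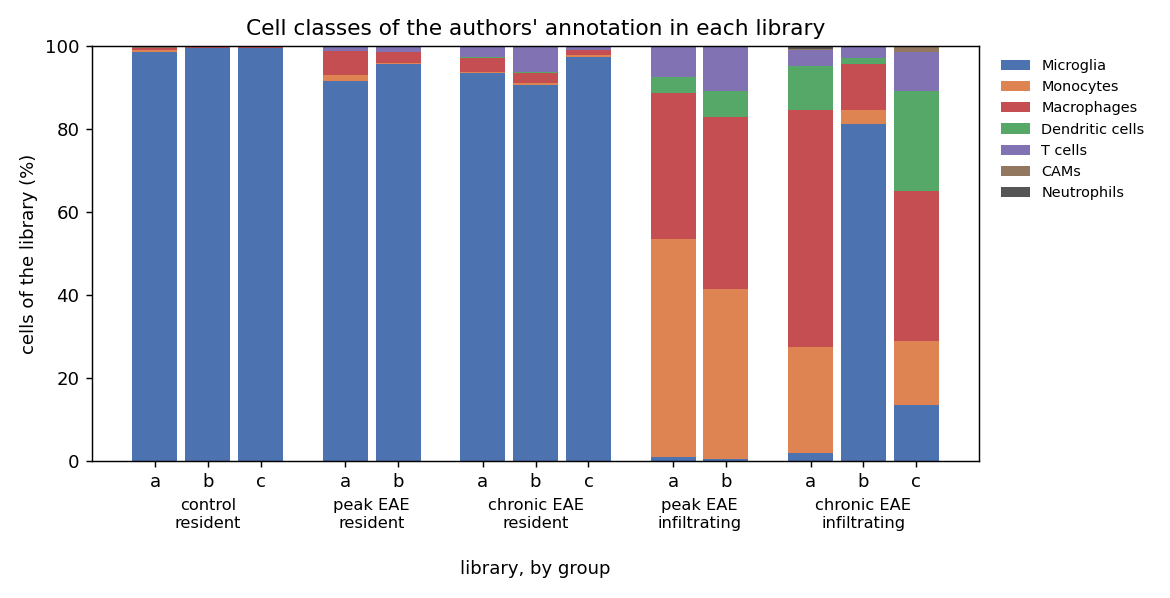
Percent of cells of each annotated class (vertical axis, stacked bars) in each of the 13 libraries (horizontal axis, by group). Microglia fill at least 90.6% of every resident library, and 81.2% of chronic infiltrating library b.

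Resident cells at the peak of EAE were compared with those of healthy controls. Cxcl9, a chemokine that draws T cells, was at 520 ± 69.6 CPM at the peak (n = 2) and 0.815 ± 0.514 CPM in controls (n = 3), a log2 fold change of 9.26 ± 0.65 (adjusted p = 1.59e-05). Slamf7, a receptor of activated leukocytes, was higher by 6.25 ± 0.39 (adjusted p = 9.8e-06). P2ry14, a receptor for UDP-glucose, and Hpse, which cleaves heparan sulfate, were higher by 7.63 ± 0.57 and 7.20 ± 0.59. Fgl2 and Cybb, the catalytic subunit of the phagocyte NADPH oxidase, were higher by 4.46 ± 0.37 and 4.30 ± 0.36. Cybb was at 327 ± 76.2 CPM against 16.6 ± 5.03 CPM. The genes lower with the smallest p were Cd300a (-2.56 ± 0.27), the transcription factor gene Sox4 (-4.75 ± 0.55), the lipopolysaccharide co-receptor gene Cd14 (-2.63 ± 0.35), Clec4a2 (-3.21 ± 0.46), Cysltr1 (-1.94 ± 0.28) and Tm6sf1 (-2.35 ± 0.36). Their adjusted p ran from 1.92e-04 for Cd300a to 0.00177 for Tm6sf1.

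Of 22 interferon response genes measured, 16 rose and 0 fell at the peak (22 and 0 adjusted over the list alone). Their median log2 fold change was 2.91, with a camera adjusted p of 1.64e-14, and adjusted p = 0.256 with an estimated correlation. Iigp1, an interferon-inducible GTPase gene, reached 995 ± 87.4 CPM against 2.88 ± 2.02 CPM, and Bst2 rose by 2.05 ± 0.30. Of 15 MHC class I genes 12 rose (15 adjusted over the list alone), among them H2-K1 (3.22 ± 0.35) and the peptide transporter gene Tap1 (2.94 ± 0.36). The list had a median of 2.17 and an adjusted p of 5.28e-14, and adjusted p = 0.216 with an estimated correlation. Of 11 MHC class II genes 8 rose (9 adjusted over the list alone). Their median was 1.84 and their adjusted p 1.27e-07, and adjusted p = 0.216 with an estimated correlation. H2-Ab1 was at 3499 ± 542 CPM against 64.4 ± 27.0 CPM, and Ciita, the master regulator of MHC class II genes, at 124 ± 36.7 CPM against 0.627 ± 0.219 CPM. H2-Aa and Cd74 rose by 5.53 ± 0.72 and 5.02 ± 0.80. Cytokine and chemokine genes moved both ways, with 10 of 23 higher and 2 lower (11 and 3 adjusted over the list alone). That list had an adjusted p of 4.25e-04, and adjusted p = 0.311 with an estimated correlation. Tnf rose by 3.55 ± 0.60 and Il6 fell by 4.35 on the log2 scale (SE 0.97, adjusted p = 0.0114), on 10 UMIs at the peak and 523 in controls.

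Proliferation genes rose for 14 of 20 at the peak (17 adjusted over the list alone). Their median was 2.21, with an adjusted p of 5.29e-09, and adjusted p = 0.33 with an estimated correlation. Mki67, a marker of cycling cells, was at 43.0 ± 6.88 CPM against 6.20 ± 2.82 CPM, and the replication clamp gene Pcna rose by 1.25 ± 0.23. Of 21 genes of disease-associated microglia, a state described in neurodegeneration, 10 rose and 1 fell (13 and 1 adjusted over the list alone). Their median was 1.67 and their adjusted p 1.08e-04, and adjusted p = 0.216 with an estimated correlation. Apoe, which encodes a lipid carrier, was at 11446 ± 2256 CPM against 1338 ± 107 CPM. Gpnmb, Itgax and Axl rose by 5.46 ± 0.75, 3.01 ± 0.41 and 3.12 ± 0.49, and Ank fell by 2.41 (SE 0.69, adjusted p = 0.0338). Homeostatic microglial genes had a median of -1.39 (adjusted p = 2.36e-04, and adjusted p = 0.387 with an estimated correlation). Of the 16, 3 were called lower (5 adjusted over the list alone), Fcrls (-4.83 ± 0.81), Selplg (-2.06 ± 0.49) and Gpr34 (-3.97 ± 1.14). The purinergic receptor gene P2ry12 was at 251 ± 38.3 CPM against 2352 ± 635 CPM and was not called over all cells (adjusted p = 0.0628), and was called among annotated microglia alone (adjusted p = 3.61e-04). T cell markers were higher for 5 of 8 and lower for 1 at the peak (6 and 1 adjusted over the list alone). Their adjusted p was 0.0461, and adjusted p = 0.424 with an estimated correlation. Among annotated microglia alone the T cell list gave an adjusted p of 0.987 with the opposite direction. Natural killer cell markers were higher for 2 of 6 (5 adjusted over the list alone; adjusted p = 0.0141, and adjusted p = 0.357 with an estimated correlation). Monocyte markers were higher for 2 of 12 (2 adjusted over the list alone; median 1.79, adjusted p = 0.00847, and adjusted p = 0.402 with an estimated correlation). Of neutrophil and B cell markers 0 of 10 and 0 of 3 were called by edgeR, and of 11 dendritic cell markers 2 were higher and 1 lower (adjusted p = 0.887, 0.226 and 0.887). Of 10 border-associated macrophage markers 2 were higher and 2 lower (2 and 5 adjusted over the list alone; median -2.97, adjusted p = 0.169). The median mitochondrial percent per cell was 2.65 and 2.30 in the peak and 1.09, 1.46 and 1.09 in the control libraries. Genes induced by dissociation rose for 6 of 19 (6 adjusted over the list alone; median 0.65, adjusted p = 0.0038, and adjusted p = 0.357 with an estimated correlation). Oligodendrocyte markers fell for 2 of 7 (3 adjusted over the list alone; median -1.97, adjusted p = 0.0229, and adjusted p = 0.357 with an estimated correlation). Astrocyte markers fell for 3 of 7 and neuron markers for 1 of 4 (3 and 3 adjusted over the list alone), with adjusted p = 0.0141 and 0.0230, and adjusted p = 0.216 and 0.357 with an estimated correlation. The summed CPM of astrocyte markers was 183 ± 54.9 at the peak against 133 ± 18.7 in controls, the other way from the called members.

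**Figure D2:**
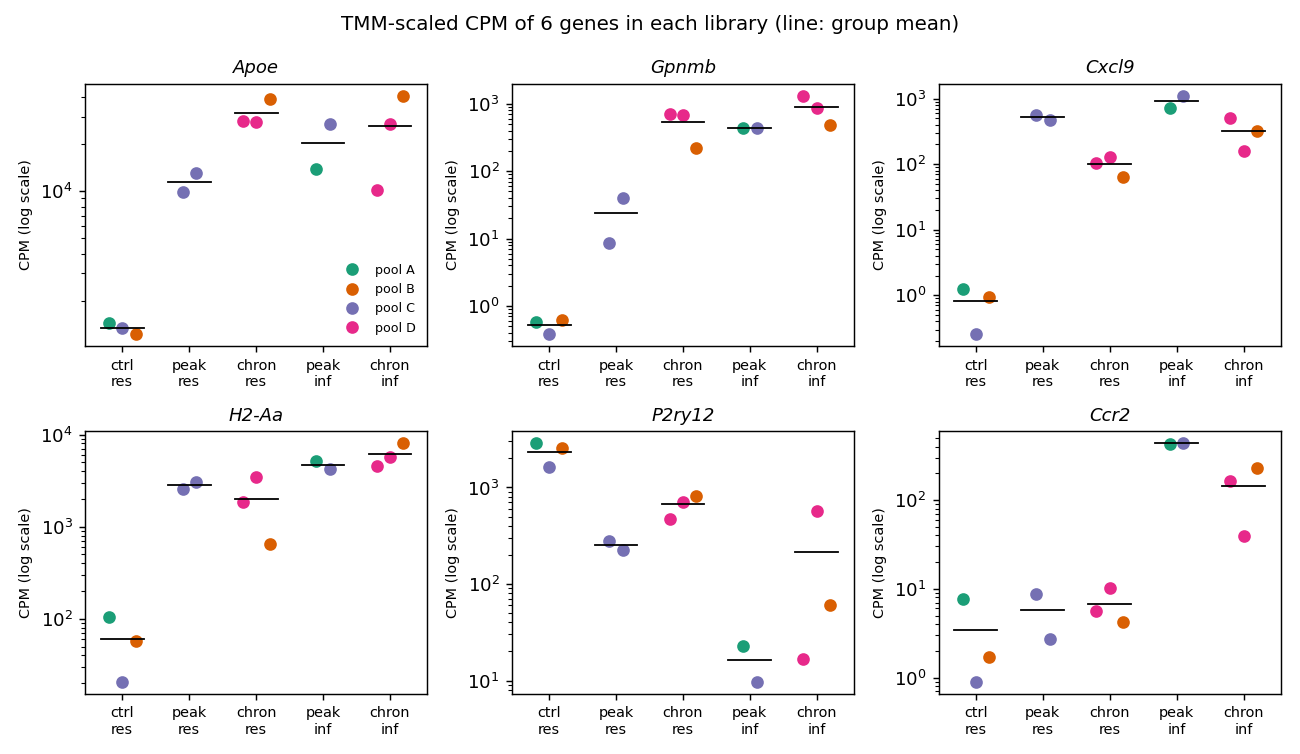
TMM-scaled CPM on a log axis of Apoe, Gpnmb, Cxcl9, H2-Aa, P2ry12 and Ccr2 in each library, by group and coloured by sequencing pool, with a line at the group mean. Cxcl9 averaged 520 CPM in peak resident and 99.2 CPM in chronic resident libraries, against 0.815 CPM in controls.

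Nuclear-encoded complex I subunits had, as a list, a median log2 fold change of 0.51 over 36 genes (camera adjusted p = 0.00159, and adjusted p = 0.552 with an estimated correlation). Of these, 1 was called (1 adjusted over the list alone), Ndufs6, at 102 ± 25.6 CPM against 43.6 ± 3.98 CPM. The list was not called without peak library b (adjusted p = 0.721, median 0.09). It was called without each other library of these groups, with adjusted p of 4.73e-08 without peak library a and from 1.46e-04 to 0.0276 without a control. Its median was 0.88 with the pool as a term and 0.20 on library size only. In pool C, summed CPM of the subunits was 3696 in control b, 3934 in peak library a and 5354 in peak library b. Assembly factors of complex I had a median of -0.04 (adjusted p = 0.693, 0 of 15 called). For complexes II, III, IV and V, 0 of 4, 1 of 9, 3 of 11 and 2 of 17 genes rose (2, 2, 8 and 2 adjusted over the list alone), with medians of 0.72, 0.41, 0.89 and 0.70. The adjusted p was 0.0617, 0.0385, 2.36e-04 and 1.08e-04, and the last 3 had adjusted p = 0.498, 0.379 and 0.387 with an estimated correlation. Glycolysis genes rose for 3 of 18 (9 adjusted over the list alone; median 1.15, adjusted p = 8.20e-04, and adjusted p = 0.387 with an estimated correlation). Antioxidant genes rose for 4 of 19 (8 higher and 1 lower adjusted over the list alone; median 0.85, adjusted p = 0.00129, and adjusted p = 0.357 with an estimated correlation).

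At the peak 1821 of 11787 genes were called in resident cells, 1067 higher and 754 lower. With the sequencing pool as a term 778 were called (508 higher, 270 lower), of which 676 were among the 1821. On library size only 763 were higher and 1482 lower, with the median of all genes at -0.30. Leaving out control a, control c, peak library a or peak library b gave 922, 723, 614 and 449 calls. Of 33 named calls, 30 were kept without control a (Ank, Gpr34 and Ndufs6 lost), 32 without control b (Ank), and 30 without control c (Ank, Gpr34 and Ndufs6). Without peak library a 30 were kept (Ank, Selplg and Gpr34 lost) and without peak library b 27 (Pcna, Ank, Selplg, Gpr34, Il6 and Ndufs6). Kept were 28 with the pool as a term (Mki67, Ank, Selplg, Gpr34 and Ndufs6 lost).

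Resident cells of chronic EAE were compared with the same controls. Apoe (chromosome 7, 19696109 to 19699188 on the minus strand, GRCm38) reached 31610.0 ± 6356 CPM in chronic (n = 3) against 1338 ± 107 CPM in control libraries (n = 3), a log2 fold change of 4.56 ± 0.52 (adjusted p = 2.57e-04). Gpnmb, a glycoprotein of lipid-laden macrophages, was at 533 ± 269 CPM against 0.525 ± 0.125 CPM (9.92 ± 0.82, adjusted p = 4.09e-05). Spp1, which encodes osteopontin, was at 5626 ± 622 CPM against 84.6 ± 47.0 CPM. Slamf7, Ms4a7, Hpse, Sash1 and P2ry14 were also among the higher genes with the smallest p, by 6.71 ± 0.39, 4.90 ± 0.33, 7.46 ± 0.58, 4.12 ± 0.33 and 6.48 ± 0.54. The lower genes with the smallest p were the transcription factor gene Klf7 (-2.02 ± 0.24), Cd164 (-1.88 ± 0.31), Tm6sf1 (-1.79 ± 0.30), Lrba (-3.34 ± 0.58), Sh2b3 (-1.54 ± 0.28) and Commd8 (-1.32 ± 0.24). Their adjusted p ran from 3.62e-04 to 0.00367.

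Of 21 disease-associated microglial genes 17 rose and 0 fell (19 and 0 adjusted over the list alone), with Lgals3 higher by 4.66 ± 0.50 and Itgax by 3.31 ± 0.40. The median was 2.64 and the adjusted p 8.58e-15, and adjusted p = 0.0602 with an estimated correlation. Lipid and lysosome genes rose for 10 of 18 (14 adjusted over the list alone), with a median of 1.46 (adjusted p = 3.85e-07, and adjusted p = 0.0846 with an estimated correlation). Among them were Nceh1, a cholesterol ester hydrolase gene, and Npc2, which moves cholesterol out of lysosomes (2.21 ± 0.23 and 1.60 ± 0.29). MHC class I, MHC class II and interferon response genes rose for 11 of 15, 5 of 11 and 9 of 22 (12, 6 and 19 adjusted over the list alone). These lists had medians of 1.72, 1.11 and 2.01 and adjusted p of 8.49e-10, 1.63e-05 and 1.04e-08, and adjusted p = 0.325, 0.364 and 0.364 with an estimated correlation. H2-D1 rose by 2.74 ± 0.35, Cd74 by 5.81 ± 0.81, H2-Aa by 5.03 ± 0.69, Iigp1 by 5.22 ± 0.76, and Cxcl9 by 6.87 ± 0.59. Cybb was at 180 ± 10.8 CPM against 16.6 ± 5.03 CPM, and 2 of 6 NADPH oxidase genes rose (3 adjusted over the list alone; median 0.59, adjusted p = 0.126). Homeostatic microglial genes had a median of -1.29 (adjusted p = 0.00199, and adjusted p = 0.575 with an estimated correlation). Selplg, P2ry13 and Siglech were the 3 of 16 called lower (4 adjusted over the list alone), by -1.63 ± 0.41, -2.22 ± 0.58 and -2.28 ± 0.70. P2ry12, at 667 ± 179 CPM against 2352 ± 635 CPM, had an adjusted p of 0.172, and 0.00669 among annotated microglia. T cell markers were higher for 7 of 8 and lower for 1 (7 and 1 adjusted over the list alone; adjusted p = 0.00512, and adjusted p = 0.443 with an estimated correlation). Natural killer cell markers were higher for 5 of 6 (6 adjusted over the list alone; adjusted p = 0.00715, and adjusted p = 0.398 with an estimated correlation). Monocyte markers were higher for 3 of 12 (4 adjusted over the list alone; median 1.33, adjusted p = 0.0119, and adjusted p = 0.575 with an estimated correlation). Their summed CPM was 692, 518 and 151 in chronic libraries a, b and c against 143, 37.9 and 24.5 in controls a, b and c. Among annotated microglia alone that list had an adjusted p of 0.466, and 37 of 37 named calls were kept. Border-associated macrophage markers were higher for 3 of 10 and lower for 1 (3 and 2 adjusted over the list alone; adjusted p = 0.951), and genes induced by dissociation higher for 2 of 19 and lower for 2 (3 and 2 adjusted over the list alone; adjusted p = 0.291). Of neutrophil, dendritic cell, B cell and astrocyte markers 1 each of 10, 11, 3 and 7 was higher (1, 0, 1 and 1 adjusted over the list alone), with adjusted p of 0.675, 0.898, 0.606 and 0.951.

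Of 36 nuclear-encoded complex I subunits 13 rose and 0 fell in chronic against control resident cells (22 and 0 adjusted over the list alone), with a median log2 fold change of 0.84 (adjusted p = 8.49e-10, and adjusted p = 0.398 with an estimated correlation). Among 10000 random lists matched on mean expression and transcript length, whose median was 0.66, the value of 0.84 lay at percentile 92.96. Ndufa1 was at 350 ± 122 CPM against 85.5 ± 23.7 CPM (2.03 ± 0.37), and Ndufa2, Ndufc1 and Ndufb5 rose by 1.09 ± 0.24, 1.73 ± 0.41 and 1.09 ± 0.26. The median was 0.74 to 1.02 with any single library of these groups left out, and 0.37 on library size only. With the pool as a term it was 0.43 (adjusted p = 1.30e-04) with 0 of 36 called by edgeR, and Ndufa1, Ndufa2, Ndufc1, Ndufb5, Uqcrh, Cox8a and Atp5e each lost the call, with adjusted p from 0.160 to 0.670. They also lost it with that term over annotated microglia alone. In pool B, summed CPM of the subunits was 4360 in control c and 4679 in chronic library c, whereas chronic libraries a and b, both in pool D with no control, were at 6571 and 6617. Of 4 complex II genes 1 rose (1 adjusted over the list alone), and their median of 0.34 (adjusted p = 0.306) flipped to -0.14 on library size only. Complex III, IV and V genes rose for 4 of 9, 10 of 11 and 12 of 17 (7, 11 and 15 adjusted over the list alone), including Uqcrh (1.44 ± 0.25), Cox8a (1.49 ± 0.29) and Atp5e (1.40 ± 0.30). Their medians were 1.05, 1.24 and 1.16 and their adjusted p 1.51e-04, 1.93e-07 and 6.62e-08, and adjusted p = 0.371, 0.364 and 0.364 with an estimated correlation. Of 18 glycolysis genes 11 rose (13 adjusted over the list alone; median 1.52, adjusted p = 8.57e-06, and adjusted p = 0.364 with an estimated correlation). Pgk1 and Aldoa were higher by 2.57 ± 0.47 and 2.42 ± 0.46. Antioxidant genes rose for 7 of 19 (12 higher and 2 lower adjusted over the list alone; adjusted p = 1.71e-04, and adjusted p = 0.364 with an estimated correlation). Prdx1, a peroxiredoxin gene, was higher by 2.46 ± 0.43. Genes of the tricarboxylic acid cycle had 0 of 14 called by edgeR and a median of 0.17 (adjusted p = 0.631), which flipped to -0.31 on library size only.

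**Figure D3:**
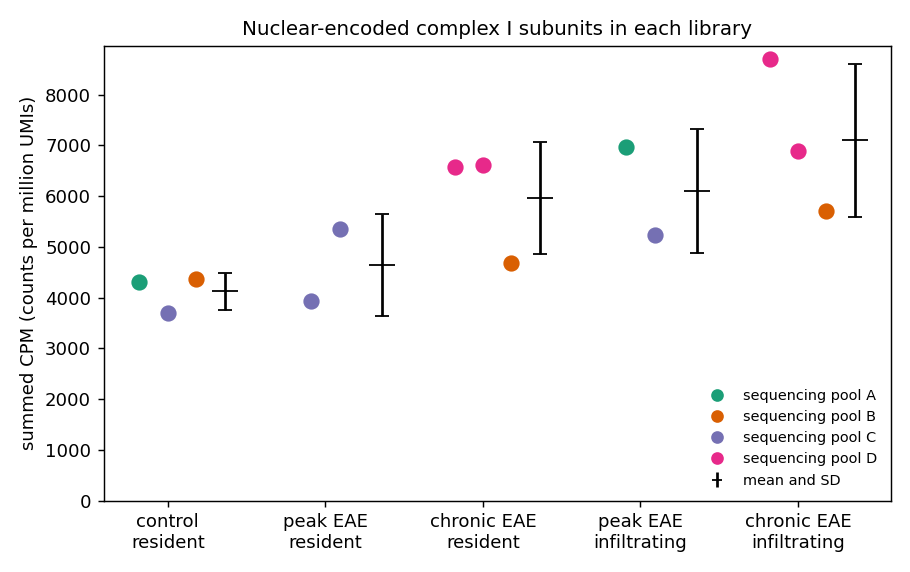
Summed CPM of the nuclear-encoded complex I subunits, on library size only, in each library (points, coloured by sequencing pool) and as mean and SD of each group (horizontal axis). Group means ran from 4120 in control to 5956 in chronic resident and 7095 in chronic infiltrating libraries.

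In resident cells of chronic EAE 1696 genes were called against control, 1218 higher and 478 lower. On library size only 834 were higher and 2700 lower, with the median of all genes at -0.47. With the pool as a term 67 were called (64 higher, 3 lower), all among the 1696, and 12 of 37 named calls were kept. Without chronic libraries a, b or c the counts were 647, 666 and 2828, and without controls a, b or c 924, 712 and 670. Named calls kept were 31 of 37 without chronic library a and 31 without b (in each case Ndufa2, Ndufc1, Ndufb5, Selplg, P2ry13 and Siglech lost). They were 33 without control a (Ndufb5, Selplg, P2ry13 and Siglech lost), 30 without control b (those 4, Ndufa2, Ndufc1 and Atp5e) and 34 without control c (Selplg, P2ry13 and Siglech).

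Resident cells were compared between chronic EAE and the peak. Igf1, a growth factor gene, was at 131 ± 25.1 CPM in chronic (n = 3) and 1.85 ± 1.55 CPM in peak libraries (n = 2), a log2 fold change of 6.18 ± 0.95 (adjusted p = 0.0115). It was at 107 CPM in chronic library c and 2.78 in the control of its pool, against 2.95 and 0.757 in the peak libraries and 3.06 in the control of theirs. Spp1 was at 5626 ± 622 against 218 ± 210 CPM and Gpnmb at 533 ± 269 against 24.1 ± 22.0 CPM. The higher genes with the smallest p were Ms4a7 (3.63 ± 0.37), Cd300a (2.67 ± 0.27), Fam20c (3.11 ± 0.38), the urokinase gene Plau (2.72 ± 0.35), Dhrs3 (2.06 ± 0.27) and Rftn1 (2.08 ± 0.29). Their adjusted p ran from 0.00105 to 0.00717. Those lower were Fgl2 (-2.43 ± 0.34), Ciita (-3.75 ± 0.60), Coro7 (-1.58 ± 0.27), the guanylate-binding protein genes Gbp3 and Gbp5 (-2.44 ± 0.44 and -3.07 ± 0.58) and Naaa (-1.97 ± 0.36). Fcrls, a homeostatic microglial gene, was at 1054 ± 432 CPM against 31.6 ± 13.9 CPM.

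Disease-associated microglial genes were higher in chronic than peak resident cells for 5 of 21 (12 adjusted over the list alone; median 1.27, adjusted p = 1.76e-06, and adjusted p = 0.275 with an estimated correlation), including Ank (3.66 ± 0.72). Apoe, at 1.47 ± 0.53, was not called (adjusted p = 0.114). The next 4 lists each had adjusted p = 0.643 with an estimated correlation. Interferon response genes fell for 4 of 22 (6 adjusted over the list alone; median -0.92, adjusted p = 2.13e-05) and MHC class I genes for 2 of 15 (8 adjusted over the list alone; median -0.72, adjusted p = 9.94e-04). MHC class II genes fell for 1 of 11 (2 adjusted over the list alone; median -0.56, adjusted p = 0.0161) and proliferation genes for 2 of 20 (3 adjusted over the list alone; median -0.89, adjusted p = 1.75e-05). The summed CPM of MHC class II genes was 34478 ± 15400 in chronic against 32516 ± 4854 in peak libraries, the other way from the median. Iigp1 was at 107 ± 67.2 CPM against 995 ± 87.4 CPM. Stat2, a transducer of interferon signals, fell by 2.16 (SE 0.45), Cxcl9 by 2.39 (SE 0.48), Mki67 by 2.40 (SE 0.52) and Hmgb2 by 1.61 (SE 0.38). Among antioxidant genes Sod1 and Txn1 were the 2 of 19 called, both lower (3 adjusted over the list alone), by -1.32 ± 0.26 and -1.60 ± 0.37. The list's median was 0.22 (adjusted p = 0.843). Border-associated macrophage markers were higher for 1 of 10 (6 adjusted over the list alone; median 3.03, adjusted p = 0.0287, and adjusted p = 0.643 with an estimated correlation). Of T cell and B cell markers 0 of 8 and 0 of 3 were called by edgeR (3 and 2 higher adjusted over the list alone), with medians of 2.10 and 2.82 (adjusted p = 0.0534 and 0.0621). Genes induced by dissociation were higher for 1 of 19 and lower for 2 (1 and 7 adjusted over the list alone; median -0.44, adjusted p = 0.0534). The median mitochondrial percent per cell was 1.00, 1.05 and 1.49 in the chronic and 2.65 and 2.30 in the peak resident libraries. Oligodendrocyte markers had a median of 2.71 with 0 of 7 called by edgeR (5 adjusted over the list alone; adjusted p = 0.0161, and adjusted p = 0.643 with an estimated correlation). Astrocyte and neuron markers had 1 of 7 and 1 of 4 called higher (5 and 4 adjusted over the list alone; adjusted p = 0.00657 and 0.0135, and adjusted p = 0.275 and 0.643 with an estimated correlation). The summed CPM of astrocyte markers was 164 ± 63.55 in chronic against 183 ± 54.9 in peak libraries, the other way from the called member. For complex I subunits 0 of 36 were called by edgeR (0 adjusted over the list alone). Their median was 0.37 (adjusted p = 0.00338, and adjusted p = 0.797 with an estimated correlation). With the pool as a term, resting on control c, it was -0.40 (adjusted p = 1.16e-04). Without peak library a the adjusted p of that list was 0.820 (median 0.10).

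Between the stages 260 genes were called in resident cells, 143 higher and 117 lower in chronic EAE. No pool held both stages, and with the pool as a term edgeR called 0 genes (406 at an unadjusted p under 0.05; DESeq2 without the term called 1099 and limma-voom 468). On library size only 61 were higher and 85 lower, with the median of all genes at -0.10. Without chronic libraries a or b the count was 39 and 31, without peak library a 7, without peak library b 1, and without chronic infiltrating library b, which shares the fit, 645. Of 24 named calls 12 were kept without chronic library a, 11 without b, 17 without c, 3 without peak library a and 0 without peak library b.

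Infiltrating cells were compared between the same stages. Il4i1, an amino acid oxidase gene of activated myeloid cells, was at 32.9 ± 5.07 CPM in chronic (n = 3) and 5.69 ± 1.18 CPM in peak libraries (n = 2), a log2 fold change of 2.56 ± 0.30 (adjusted p = 0.00869). It was not called over cells of the sorted classes (1.74, adjusted p = 0.265), and was called without microglia in the infiltrating libraries (2.38, adjusted p = 0.00676). Bhlhe41, Plau, B4galt4, Cd63 and Fcrls were higher by 4.01 ± 0.55, 2.32 ± 0.34, 2.60 ± 0.41, 2.75 ± 0.43 and 5.20 ± 0.83, and Hpgd, which degrades prostaglandins, by 4.32 ± 0.73 (adjusted p = 0.0493). The 2 genes called lower were Saa3, an acute-phase serum amyloid gene (-3.73 ± 0.62, 54.5 ± 37.4 against 731 ± 81.0 CPM), and Arid5b (-1.43 ± 0.23). Ccr2, the chemokine receptor gene of inflammatory monocytes, was at 146 ± 97.7 CPM against 435 ± 2.87 CPM and was not called (adjusted p = 0.285), nor was the arginase gene Arg1 (-0.86 ± 1.80, adjusted p = 0.834).

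Chronic infiltrating library b held 81.2% microglia. The first 6 lists given here each had adjusted p = 0.654 with an estimated correlation. Homeostatic microglial genes had a median of 3.31 in chronic against peak infiltrating libraries (1 of 16 called, 11 adjusted over the list alone; adjusted p = 2.06e-05). That median was 1.32 among annotated monocytes and macrophages alone. P2ry12 differed by 3.72 ± 1.13 over all cells and by 0.28 among those classes, without being called in either. Disease-associated genes were higher for 1 of 21 (10 adjusted over the list alone; median 1.14, adjusted p = 1.33e-05). Monocyte markers had a median of -1.42 with 0 of 12 called by edgeR (0 adjusted over the list alone; adjusted p = 1.83e-04). Interferon response, MHC class I and glycolysis genes, also with 0 called (1 interferon gene lower adjusted over the list alone), had medians of -0.61, -0.59 and -0.59 (adjusted p = 1.21e-04, 6.74e-04 and 0.0025). Complex I subunits had a median of 0.19 (adjusted p = 0.0983), which was -0.35 with the pool as a term (adjusted p = 8.17e-04). Without chronic library a it was -0.02 (adjusted p = 0.920) and without peak library b -0.17 (adjusted p = 0.224). Without chronic library b, chronic library c or peak library a the list passed, with adjusted p of 0.00839, 0.0285 and 1.46e-04.

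Between the stages 13 genes were called in infiltrating cells, 11 higher and 2 lower in chronic EAE. DESeq2 called 552 and limma-voom 11, and edgeR called 0 in a fit of only these groups (867 at an unadjusted p under 0.05; 0 of 9 named calls kept). EdgeR called 937 genes without chronic library a, 5 without b and 57 without c. Without peak library a or b edgeR called 0 (2385 and 1366 at an unadjusted p under 0.05). No pool held infiltrating libraries of both stages, and with the pool as a term edgeR also called 0 (498 at an unadjusted p under 0.05). On library size only it called 4, all higher. Of 9 named calls 9 were kept without chronic library a and without c, 4 without b (Plau, Cd63, Hpgd, Arid5b and Saa3 lost) and 0 without either peak library or with the pool as a term.

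At the peak of disease, infiltrating cells were compared with resident cells of the same stage. The monocyte gene Ccr2 (chromosome 9, 124101950 to 124113557 on the plus strand) was at 435 ± 2.87 CPM against 5.78 ± 4.32 CPM (n = 2 in each group; log2 fold change 6.25 ± 1.06, adjusted p = 0.00474). The microglial transcription factor gene Sall1 was at 0.402 ± 0.0277 CPM against 116 ± 28.5 CPM (-8.15 ± 1.47, adjusted p = 0.00568). The higher genes with the smallest p were Ms4a7 (4.72 ± 0.40), Rftn1 (2.87 ± 0.31), Myof (6.05 ± 0.67), Sash1 (3.31 ± 0.37), the C-type lectin gene Clec4d (6.64 ± 0.78) and Fam20c, with adjusted p from 3.68e-04 to 0.00157. Those lower included B4galt4 (-2.99 ± 0.43), the potassium channel gene Kcnk6 (-3.38 ± 0.52), the scavenger receptor gene Cd36 (-5.99 ± 0.95), Tjp1 (-5.96 ± 0.95) and Cox6a2 (-4.18 ± 0.67).

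Of 12 monocyte markers 11 were higher in infiltrating cells (12 adjusted over the list alone; median 5.52, adjusted p = 8.53e-07, and adjusted p = 0.349 with an estimated correlation). Ly6c2 and S100a6 were higher by 6.12 ± 1.88 and 5.72 ± 1.37. Of 16 homeostatic microglial genes 11 were lower (16 adjusted over the list alone; median -3.72, adjusted p = 6.35e-07, and adjusted p = 0.386 with an estimated correlation). Lower were Siglech (-6.24 ± 1.04), Tmem119 (-5.11 ± 1.06) and P2ry12 (-3.93 ± 1.18). Glycolysis genes were higher for 11 of 18 and lower for 1 (13 and 1 adjusted over the list alone; median 1.73, adjusted p = 1.35e-04, and adjusted p = 0.498 with an estimated correlation). Hk1, Pgam1 and the glucose transporter gene Slc2a1 were higher by 2.36 ± 0.46, 1.93 ± 0.40 and 1.74 ± 0.37, and Pfkfb3 lower (-1.02 ± 0.33, adjusted p = 0.0494). Pfkfb3 lost the call over cells of the sorted classes, with RLE size factors, limma-voom, only these groups, thinning or the pool as a term, without doublets, and without either peak infiltrating library or peak resident library a. Antioxidant genes were higher for 8 of 19 (12 higher and 1 lower adjusted over the list alone; median 1.24, adjusted p = 2.45e-04, and adjusted p = 0.349 with an estimated correlation). Gsr, Srxn1, the cystine transporter gene Slc7a11 and the mitochondrial superoxide dismutase gene Sod2 were higher by 2.83 ± 0.48, 1.99 ± 0.36, 4.15 ± 0.90 and 2.74 ± 0.61. Macrophage effector enzyme genes were higher for 3 of 8 (6 adjusted over the list alone; median 2.82, adjusted p = 0.00175, and adjusted p = 0.349 with an estimated correlation). Nos2, which encodes inducible nitric oxide synthase, was at 48.4 ± 3.40 CPM against 4.14 ± 2.22 CPM (3.56 ± 1.06, adjusted p = 0.0355). Arg1, at 1072 ± 532 against 5.79 ± 0.919 CPM, was called among cells of the sorted classes (adjusted p = 0.00323) and not over all cells (adjusted p = 0.0668).

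Disease-associated microglial genes split at the peak, with 4 of 21 higher and 4 lower in infiltrating cells (5 and 6 adjusted over the list alone; adjusted p = 0.842), and their median of -0.61 and mean of 0.04 differed in sign. Gpnmb and Lgals3 were higher by 4.18 ± 0.74 and 3.69 ± 0.59, and Cd63 (-2.39 ± 0.44), Ctsd (-1.94 ± 0.38) and Cst7 (-4.57 ± 1.28) lower. Cybb was at 968 ± 263 CPM against 327 ± 76.2 CPM (1.57 ± 0.38, adjusted p = 0.0157) and Il1b, the interleukin 1 beta gene, rose by 3.95 ± 1.09. Complex I subunits had a median of 0.64 (adjusted p = 2.15e-04, and adjusted p = 0.685 with an estimated correlation) with 0 of 36 called by edgeR over all cells (0 adjusted over the list alone) and 4 over cells of the sorted classes. The median was 0.36 with the pool as a term, and the list was not called without peak infiltrating library a (adjusted p = 0.0889) or peak resident library a (adjusted p = 0.113). T cell markers were higher in infiltrating cells for 7 of 8 (7 adjusted over the list alone; adjusted p = 6.33e-04, and adjusted p = 0.349 with an estimated correlation). Border-associated macrophage markers were higher for 5 of 10 (5 adjusted over the list alone; adjusted p = 0.00559, and adjusted p = 0.386 with an estimated correlation).

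Between infiltrating and resident cells at the peak 2220 genes were called, 1103 higher and 1117 lower, and on library size only 790 higher and 1415 lower, with the median of all genes at -0.30. With the pool as a term 721 were called (451 higher, 270 lower), 681 of them among the 2220, and over cells of the sorted classes 3434. Without peak infiltrating library a, peak resident library a or peak resident library b the count was 345, 390 and 596. Of 34 named calls 20 were kept without peak infiltrating library a, 27 without peak infiltrating library b, 20 without peak resident library a and 22 without peak resident library b. There were 27 kept with the pool as a term. Ly6c2, P2ry12, Nos2, Il1b and Cst7 were lost under each of the 4 omissions.

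Infiltrating and resident cells were also compared in chronic EAE. Klra2 was at 60.1 ± 34.6 CPM in infiltrating (n = 3) and 3.72 ± 1.24 CPM in resident libraries (n = 3), a log2 fold change of 4.02 ± 0.48 (adjusted p = 0.0117). Ms4a7, Mcemp1, Clec12a, Plbd1 and Ahnak were higher by 2.21 ± 0.29, 3.44 ± 0.47, 3.80 ± 0.57, 5.11 ± 0.80 and 3.19 ± 0.53. Of 12 monocyte markers, Ccr2 (4.46 ± 0.79), Ifitm6 (5.42 ± 1.03) and S100a4 (4.03 ± 0.86) were the 3 called (11 adjusted over the list alone; median 3.60, adjusted p = 2.58e-09, and adjusted p = 0.227 with an estimated correlation). Dendritic cell markers were higher for 4 of 11 (7 adjusted over the list alone; median 3.67, adjusted p = 1.50e-04, and adjusted p = 0.227 with an estimated correlation), among them Clec10a (5.63 ± 0.82). Border-associated macrophage markers were higher for 3 of 10 (5 adjusted over the list alone; adjusted p = 5.33e-05, and adjusted p = 0.227 with an estimated correlation), among them Mrc1 and F13a1 (2.45 ± 0.56 and 3.04 ± 0.65). Natural killer cell markers had a median of 2.33 with 0 of 6 called by edgeR (3 higher adjusted over the list alone; adjusted p = 8.60e-06, and adjusted p = 0.227 with an estimated correlation). Neutrophil markers were higher for 1 of 10 (5 adjusted over the list alone; median 3.18, adjusted p = 0.112), with a summed CPM of 2904, 875 and 44.3 in infiltrating libraries a, b and c against 412, 228 and 163 in resident libraries a, b and c. Cybb was at 578 ± 163 CPM against 180 ± 10.8 CPM (1.69 ± 0.31). MHC class II genes were higher for 2 of 11 (6 adjusted over the list alone; median 1.006, adjusted p = 3.41e-04, and adjusted p = 0.32 with an estimated correlation), including Ciita (2.56 ± 0.55). Of 18 glycolysis genes, 1 was higher (1 adjusted over the list alone; median 0.51, adjusted p = 0.0260, and adjusted p = 0.682 with an estimated correlation), Pfkp (2.10 ± 0.48). The 1 gene called lower, Fam72a (-1.50 ± 0.34, adjusted p = 0.0485), lies outside the rule for named genes and was chosen after its values were seen.

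Homeostatic microglial genes had a median of -1.67 with 0 of 16 called by edgeR over all cells (5 lower adjusted over the list alone; adjusted p = 2.33e-09, and adjusted p = 0.32 with an estimated correlation). Over cells of the sorted classes, which leave out the microglia of chronic infiltrating library b, their median was -3.31 and 14 were called. The classes come from the same expression values, so the annotation itself favours this difference, which is not a separate test. P2ry12 and Tmem119 differed by -1.63 ± 0.87 and -1.72 ± 0.75 over all cells (adjusted p = 0.343 and 0.26), and by -5.00 and -3.72 over cells of the sorted classes (adjusted p = 2.12e-06 and 8.07e-05). Complex I subunits had a median of 0.40 with 0 of 36 called by edgeR over all cells (0 adjusted over the list alone; adjusted p = 4.31e-05, and adjusted p = 0.644 with an estimated correlation). The median was 0.41 with the pool as a term, and 0.62 with 8 called over cells of the sorted classes. It was 0.18 without chronic infiltrating library a and 0.22 without chronic resident library c, and the list was called without any single library of these groups. Antioxidant genes had a median of 0.60 with 0 of 19 called by edgeR (6 adjusted over the list alone; adjusted p = 8.60e-06, and adjusted p = 0.227 with an estimated correlation). Genes induced by tissue dissociation had a median of 0.74 (0 of 19 called by edgeR, 4 adjusted over the list alone; adjusted p = 2.84e-04, and adjusted p = 0.32 with an estimated correlation).

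Between infiltrating and resident cells of chronic EAE 188 genes were called, 187 higher and 1 lower, and DESeq2 called 593 and limma-voom 132. In a fit of only these groups edgeR called 0 (1106 at an unadjusted p under 0.05), and 0 of 16 named calls were kept. Over cells of the sorted classes 2991 were called (1424 higher, 1567 lower), among them 179 of the 188, and without microglia in the infiltrating libraries 2464 (1033 higher, 1431 lower). With the pool as a term 43 were called, and on library size only 95, all higher, with the median of all genes at -0.20. Without chronic infiltrating libraries a, b or c edgeR called 63, 1859 (814 higher, 1045 lower) and 78 genes, without chronic resident libraries a or b 21 and 2, and without chronic resident library c 0 (1273 at an unadjusted p under 0.05). Of 16 named calls 9 were kept without infiltrating library a, 16 without b, 8 without c, 5 without resident library a, 1 without b and 0 without c, and 7 with the pool as a term.

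**Figure D4:**
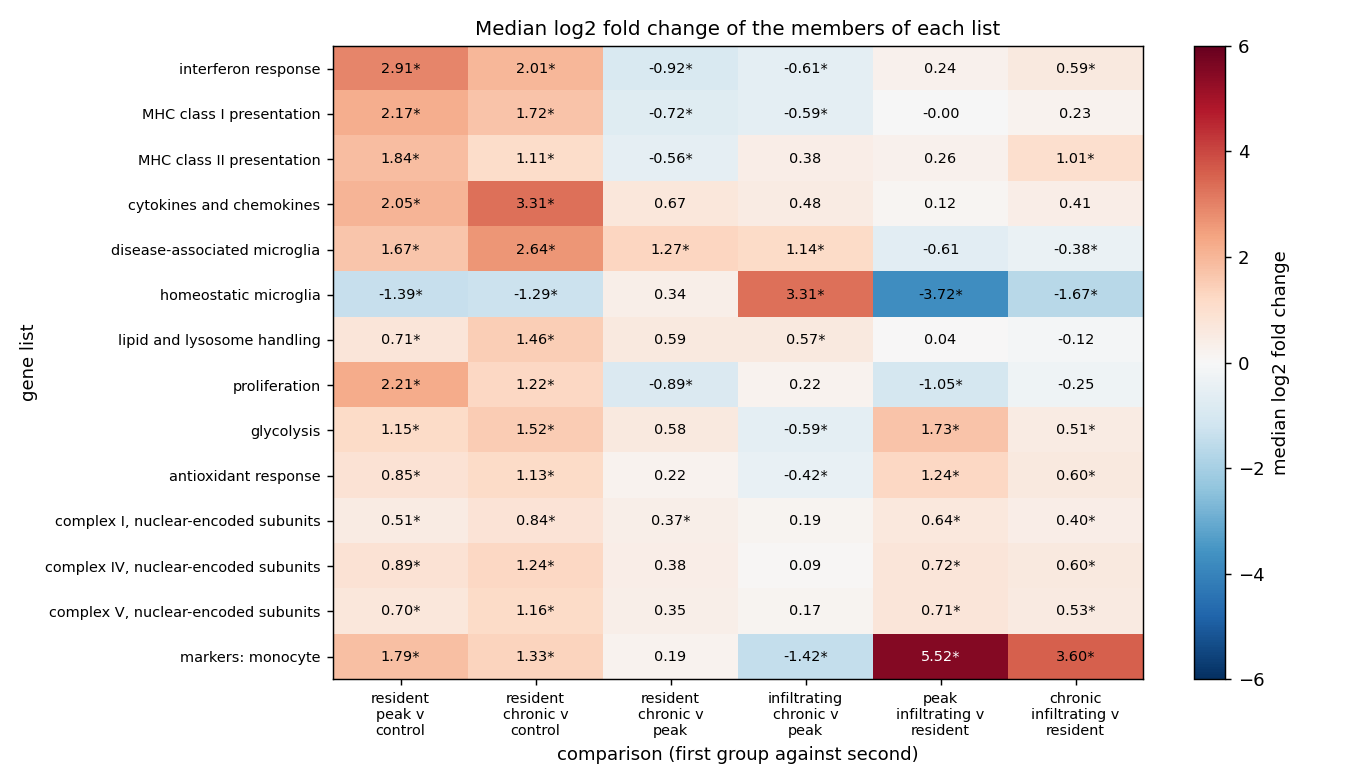
Median log2 fold change of the members of 14 gene lists (vertical axis) in the 6 comparisons of 2 groups (horizontal axis), with a star where camera's adjusted p was under 0.05 at the preset correlation. With an estimated correlation 0 of the starred lists passed; on library size only, the sign flips for interferon response genes in infiltrating against resident cells at the peak and for monocyte markers in resident chronic against peak cells.

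The change between stages was also tested for a difference between infiltrating and resident cells. Only Egln3, an oxygen-sensing prolyl hydroxylase gene (chromosome 12, 54178981 to 54203860 on the minus strand), was called by edgeR, with a difference of -4.44 ± 0.58 on the log2 scale (adjusted p = 0.0491); it lies outside the rule for named genes and was chosen after its values were seen. Its CPM was 43.1 and 22.96 in the peak infiltrating libraries and 11.5, 9.55 and 11.4 in the chronic infiltrating libraries, against 2.21 and 0.908 in the peak resident and 9.05, 8.88 and 14.002 in the chronic resident libraries. The adjusted p was 0.0179 over cells of the sorted classes and 0.284 with the pool as a term. Complex I subunits differed by a median of -0.18 (adjusted p = 0.112). With a chronic library left out, the list was called at camera's preset correlation without infiltrating a (-0.41, adjusted p = 0.00211) and resident c (-0.38, 0.00624). An estimated correlation was not run with libraries left out. Without a peak library 1 is left in its group, so only medians are given. These were -0.46 and -0.62 without infiltrating b and resident b, and 0.14 and 0.11 without infiltrating a and resident a. Leaving out chronic infiltrating library a gave 215 calls, and leaving out peak infiltrating library b 1. With any other of the 10 libraries left out edgeR called 0, with 646 to 1176 genes at an unadjusted p under 0.05. With all libraries DESeq2 called 77 genes and limma-voom 0 (949 at an unadjusted p under 0.05).

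Summed CPM of complex I subunits within annotated classes of at least 50 cells describes the level by cell type, without a test, since the classes come from the same expression values. Microglia were at 4087 ± 358 CPM in control (n = 3), 4611 ± 979 in peak (n = 2) and 5778 ± 988 in chronic resident libraries (n = 3). Different clusters held most of the microglia of these groups: cluster 9 held 92.2% of those of control libraries, cluster 3 61.5% of those of peak libraries, and clusters 1 and 4 42.0% and 38.7% of those of chronic resident libraries. T cells of chronic infiltrating libraries were at 8513 ± 1150 CPM (n = 2).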

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

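Each value here is the difference between infiltrating and resident cells in the change from peak to chronic EAE, and was singled out because the test of that difference passed. The comparisons with only cells of the sorted class were planned, and those with the sequencing pool as a term were chosen after the result was seen. Egln3 differed by -4.44 ± 0.58 on the log2 scale (adjusted p = 0.0491 by edgeR). It was at 43.1 and 22.96 CPM in peak infiltrating and 2.21 and 0.908 CPM in peak resident libraries. The adjusted p was 0.0179 with only cells of the sorted class and 0.284 with the pool as a term. Left out in turn, chronic infiltrating libraries b and c, each chronic resident library, peak infiltrating library a and each peak resident library ended the call.

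Among gene lists tested with camera, glycolysis had a median difference of -1.03 (adjusted p = 3.36e-05, and adjusted p = 0.608 with an estimated correlation). Antioxidant genes had a median difference of -0.59 (adjusted p = 0.0495, and adjusted p = 0.764 with an estimated correlation), which was not called with only cells of the sorted class (adjusted p = 0.843) or with the pool as a term (adjusted p = 0.130). Homeostatic microglial genes differed by a median of 2.11 (adjusted p = 0.00157, and adjusted p = 0.764 with an estimated correlation), with an adjusted p of 0.870 with only cells of the sorted class. MHC class II genes differed by a median of 1.27 (adjusted p = 5.41e-05, and adjusted p = 0.471 with an estimated correlation). For proliferation genes the median was 0.98 (adjusted p = 3.36e-05, and adjusted p = 0.727 with an estimated correlation). Monocyte markers had a median of -1.79 (adjusted p = 0.00599, and adjusted p = 0.727 with an estimated correlation). Their sum was 5616, 1109 and 2581 CPM in chronic infiltrating libraries a, b and c, and the microglia of b may lower this median. Oligodendrocyte markers had a median of -1.71 (adjusted p = 0.0270, and adjusted p = 0.608 with an estimated correlation).

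The remaining lists hold genes with no UMI in some group, so no median is given. Border-associated macrophage, T cell and neuron markers had adjusted p of 0.0270, 3.36e-05 and 0.00518, and adjusted p = 0.471 each with an estimated correlation. Astrocyte markers had an adjusted p of 3.36e-05, and adjusted p = 0.0787 with an estimated correlation.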

How the results depend on the processing

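Chosen after the data were seen were the pool as a term, library size only, no microglia in infiltrating libraries and paired chronic libraries. So were omitting chronic infiltrating b where it enters neither group, and libraries left out for class shares. The planned pairing by replicate number was not run. A pairing of chronic libraries c by their pool, b by the similarity of their microglia and a as those left is a hint from the data; as a replicate block it called 532 genes between infiltrating and resident cells of chronic EAE, 186 of them among the 188. The deviations of the paired libraries from their group means had correlations of 0.464 for a, -0.00357 for b and 0.323 for c, and infiltrating library b correlated best with resident library c (0.160). Of 16 named calls 15 were kept (S100a4 lost). At the preset correlation no list called in that comparison lost its call or turned, while neutrophil markers gained a call (camera adjusted p = 5.37e-04). With an estimated correlation the adjusted p of neutrophil markers was 0.317. Counts of genes were within 1.5 times the value reported in 45 of the alternatives and outside it in 84. Gene lists kept direction and call in 445, lost the call in 218, gained it in 8 and turned direction in 13. Named genes did so in 2462, 449, 32 and 0. Where no cause is given, the cause was not tested. A fit of only the groups compared, or with the pool as a term, has fewer libraries or degrees of freedom. The fit of only the groups compared nevertheless called more genes in each comparison between resident groups, and why was not tested. Thinned to the smallest library (4111257 UMIs), 11259 of 11787 genes were tested and 145 of 154 named calls kept.

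For resident peak EAE against control, 1821 genes became 3631 in a fit of only these groups and 778 with the pool as a term. Leaving out single libraries gave 449 (without peak resident b) to 2267 (without chronic infiltrating b). For resident chronic EAE against control, 1696 became 3066 with only these groups, 67 with the pool as a term, 475 with that term and only cells of the sorted class, and 3534 on library size only. Single libraries left out gave 647 (without chronic resident a) to 2828 (without chronic resident c).

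For chronic against peak EAE in resident cells, 260 became 1099 with DESeq2, 468 with limma-voom, 551 with no filter, 1358 with only these groups and 1124 with only cells of the sorted class. It became 169 after thinning, 146 on library size only and 858 without microglia in the infiltrating libraries. EdgeR called 0 with the pool as a term (406 at an unadjusted p under 0.05), and with that term and only cells of the sorted class 1. The range over left-out libraries was 1 (without peak resident b) to 645 (without chronic infiltrating b). In infiltrating cells, 13 became 552 with DESeq2, 289 with no filter, 91 with only cells of the sorted class, 5 after thinning, 4 on library size only and 24 without microglia. It became 1 with the pool as a term and only cells of the sorted class. EdgeR called 0 with only these groups (867 at an unadjusted p under 0.05) and 0 with the pool as a term (498). Single libraries left out gave 0 (without peak infiltrating a, 2385 at an unadjusted p under 0.05, or b, 1366) to 937 (without chronic infiltrating a).

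For infiltrating against resident cells at the peak, 2220 became 3434 with only cells of the sorted class and 721 with the pool as a term. Over left-out libraries it ran from 345 (without peak infiltrating a) to 2777 (without chronic infiltrating b). In chronic EAE, 188 became 593 with DESeq2, 403 with no filter, 2991 with only cells of the sorted class, 43 with the pool as a term, 4292 with both of these, 95 on library size only and 2464 without microglia. EdgeR called 0 with only these groups (1106 at an unadjusted p under 0.05). Single libraries left out gave 0 (without chronic resident c, 1273 at an unadjusted p under 0.05) to 1859 (without chronic infiltrating b). For the difference of stage changes between origins, 1 gene became 77 with DESeq2, 5 with no filter, 5 with only cells of the sorted class and 7 with that and the pool as a term. EdgeR called 0 with RLE size factors, without doublets, after thinning, with the pool as a term and on library size only (1030, 1017, 860, 736 and 962 at an unadjusted p under 0.05), and limma-voom called 0 (949). Left-out libraries moved it from 0 (8 of 10 libraries, 646 to 1176 at an unadjusted p under 0.05) to 215 (without chronic infiltrating a).

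For the complex I list, the adjusted p for resident peak EAE against control was 0.552 with an estimated correlation, 0.226 with fry, and 4.73e-08 (without peak resident a) to 0.721 (without peak resident b). For resident chronic EAE against control it was 0.398 with an estimated correlation. In resident chronic against peak EAE it was 0.797 with an estimated correlation, 0.387 with fry, and 4.10e-08 (without peak resident b) to 0.820 (without peak resident a). There the direction turned with the pool as a term (adjusted p = 1.16e-04) and with that term and only cells of the sorted class (adjusted p = 2.04e-06). In infiltrating chronic against peak EAE it was 0.00321 with only cells of the sorted class, and the direction turned with the pool as a term, without and with only these cells (adjusted p = 8.17e-04 and 0.00365). Single libraries left out gave 1.46e-04 (without peak infiltrating a) to 0.920 (without chronic infiltrating a, direction turned), and the direction also turned without peak infiltrating b (adjusted p = 0.224). For infiltrating against resident cells at the peak it was 0.685 with an estimated correlation, 0.252 with fry, and 1.50e-08 (without peak resident b) to 0.113 (without peak resident a). In chronic EAE these were 0.644 with an estimated correlation and 0.450 with fry. For the difference between origins, the direction turned with the pool as a term (adjusted p = 0.808; with only cells of the sorted class 0.0145), and left-out libraries gave 1.08e-05 (without peak resident b) to 0.639 (without chronic infiltrating c).

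Direction also turned for T cell markers at the peak against control with only cells of the sorted class (adjusted p = 0.987). It turned for lipid and lysosome genes in infiltrating chronic against peak EAE with the pool as a term (adjusted p = 0.994), and for antioxidant genes in the difference between origins with that term and only cells of the sorted class (adjusted p = 0.813). Summed complex I CPM over classes of at least 20 cells was 6224 in dendritic cells and 6548 in T cells of peak infiltrating libraries and 8239 in T cells of chronic resident libraries. The microglial share of chronic minus peak resident libraries ran from -1.84 to 2.29 (without peak resident a and b).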

Other observations

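The split of the libraries and the comparison with matched random lists were planned, and the tests of the sequencing pool, TMM scaling, label swap, shared barcodes, microglial source and depth were chosen after the result was seen. Against control, 12 of 23 cytokine and chemokine genes rose and 1 fell in resident cells of chronic EAE (17 and 3 adjusted over the list alone). Their median was 3.31, with an adjusted p of 9.07e-06, and adjusted p = 0.325 with an estimated correlation. Of 8 macrophage effector enzyme genes 3 rose (4 adjusted over the list alone; median 3.56, adjusted p = 0.00715, and adjusted p = 0.364 with an estimated correlation). Proliferation genes rose for 7 of 20 (8 adjusted over the list alone; median 1.22, adjusted p = 0.00659, and adjusted p = 0.608 with an estimated correlation). Their summed CPM was 1291, 1145 and 555 in chronic libraries a, b and c against 728, 725 and 636 in controls a, b and c. Chronic library c thus lay below every control.

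At the peak against control, 8 of 18 lipid and lysosome genes rose (9 adjusted over the list alone; median 0.71, adjusted p = 0.00105, and adjusted p = 0.216 with an estimated correlation). In infiltrating against resident cells at the peak, MHC class II genes had a median of 0.26 and a mean of -0.30 (adjusted p = 0.786). In resident cells of chronic against peak EAE, effector enzyme genes had a median of -0.94 and a mean of 0.61 (adjusted p = 0.482).

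Of 36 nuclear complex I subunits 13 were called higher in chronic EAE than in control resident libraries, with a median log2 fold change of 0.84 (adjusted p = 8.49e-10, and adjusted p = 0.398 with an estimated correlation). The median lay at percentile 92.96 of matched random lists, whose 95th percentile was 0.86. A shift shared by genes of the same abundance and length may thus account for it. Scaling alone is argued against, since on library size only the mean summed CPM was 1.446 times that of controls. Every chronic library lay above every control (4679 against 4360 in pool B). There the median fell to 0.37, so scaling may make up part. With the pool as a term the median was 0.43. The pool cannot be told apart from the disease for the 2 chronic libraries whose pool held no control. A disease effect on complex I genes in particular stays open and was not tested apart from these.

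Microglia were 81.2% of chronic infiltrating library b. A swap with a resident library is argued against, since no resident library held more than 7.156% monocytes and macrophages, and so are barcodes carried over, since at most 0.1044% of its microglial barcodes recurred in a resident library of its pool. Its microglia differed from those of chronic resident library b by a mean chi-square per gene of 1.844, against 7.971 for the closest pair of resident libraries of the same group, so microglia of the same source may have entered the infiltrating gate. The 74 microglia of chronic infiltrating library c likewise lay closest to chronic resident library c (1.578, against 6.241 and 6.467 for a and b), so such a match is not particular to library b and does not account for its larger share. Loss of the red mark in resident microglia was not tested.

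Of the 260 genes called between chronic and peak EAE resident libraries, 155 were still called after thinning to the smallest library. This argues against the library total as the whole cause. Thinning left depth per cell as it was, so that depth was not tested. Median UMIs per cell were 8614 to 8648 in peak and 2558 to 3560 in chronic resident libraries. With the pool as a term edgeR called 0 (406 of all genes at an unadjusted p under 0.05; DESeq2 and limma-voom without the term 1099 and 468), as the median fold of the 260 in the direction of the call went from 1.91 to 1.32 and its median SE from 0.38 to 0.55. For chronic library c, the control of its pool was set against the control of the peak pool. In 12.31% of the 260 genes these controls differed in the direction of the call by at least 50% of the stage difference. The stage difference was that of chronic library c from the peak libraries (medians 0.42 for the controls and 1.87 for the stages). The 260 genes were chosen by a difference that includes chronic library c, which by itself lowers this share. The share therefore cannot decide whether the pool is the whole cause. The controls differed in the direction of the call for 222 of the 260, so the pool may make up part of the stage difference. For chronic libraries a and b the pool and the stage cannot be told apart, since their pool held no control, and a difference of stage stays open as untested.

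For resident chronic EAE against control the real split of the 6 libraries called 1696 genes, and the highest of the other splits called 0 by edgeR, so 1 of 10 splits called as many. For infiltrating against resident cells in chronic EAE the real split called 188 and the highest other 0, again 1 of 10. With 10 splits no share under 0.05 can be reached.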
